A study of Mus musculus with 8 samples.

How the data were processed

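RNA was sequenced from 8 cultures of mouse pre-B cells without Arf, sorted for GFP after lentiviral transduction. There were 4 groups of 2: the empty vector, HA-tagged full-length ZNF384, TAF15-ZNF384 and TCF3-ZNF384. The series design describes the replicates as biological, and the labels describe stranded total RNA libraries. The deposited values are raw counts, read assignments per gene that the authors made with HTSeq 0.6.1p1 on the mm9 genome build according to their processing notes. The aligner and the strand setting of the count step were not available here. The values were whole numbers in every library, and no column was left out.

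Totals ran from 9381954 to 41483660 counts per library. The table held 32499 genes, of which 10419 had no count in any library. The 13 mitochondrial genes summed to 0, so no mitochondrial share was computed. A floor of 3 counts over a group stood for a group at 0, and folds against it are written as lower bounds. Where the lower group held 1 to 3 counts, the ratio is given with its exact binomial interval at 95%. Intervals and floors cover counting error only.

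Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed edgeR's expression filter by group (filterByExpr), which left 12970, and libraries were scaled by TMM. A quasi-likelihood model with 1 term per group and robust dispersion was fitted to the 8 libraries together, with 4 residual degrees of freedom and a biological coefficient of variation of 0.0958. The 6 pairwise comparisons were each tested with the quasi-likelihood F test, 2-sided, and p was adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. "Rose" and "fell" are used of genes and lists past that threshold. Normalised counts are CPM values on the TMM-scaled library sizes and are given as mean ± SD with n = 2, and log2 fold changes are given ± SE from the fit. No replicate term was used. Deviations within groups of libraries with the same replicate number correlated weakly between groups. The correlations were all positive, from 0.014 to 0.22, the highest for the empty vector with TCF3-ZNF384. They do not exclude a pairing by replicate number.

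The 27 gene lists were fixed before the data were examined, from general knowledge and not from these samples. They covered B lineage and pre-B cell, mature B and plasma cell, MHC class II, myeloid, macrophage, stem and progenitor, T and NK cell, erythroid and megakaryocyte, stromal, and matrix genes. Others held genes linked to ZNF384-rearranged leukaemia, the E protein and Id network, IL-7 and JAK-STAT signalling, pre-B cell receptor signalling, the p53 pathway, the interferon response, and NF-kB and inflammatory genes. The rest were S phase, G2 and M phase, MYC targets, replication-dependent histones, ribosomal protein genes, nuclear-encoded oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, the unfolded protein and integrated stress response, and immediate early genes. Each list was compared with the other tested genes by camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. The test was repeated with an estimated correlation, and none of the calls held with it. Where a list held a gene at 0 counts in a group, its median was also computed with that gene at its bound and without genes at or under the floor in both groups.

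The genes named were chosen by a rule written before the data were examined. It took Zfp384, Taf15, Tcf3 and Cdkn2a, and, in each comparison with the empty vector, the 8 largest changes per direction among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. The other comparisons took 5 per direction. In each list described, it took up to 3 members per direction with the smallest adjusted p. Among the genes changed by both fusions over both controls, it took the 6 per direction whose smallest change was largest. Gene models without a proper name were counted and not named. The text prints part of the genes the rule took. Coordinates are those of the mm9 assembly (NCBIM37) in the GENCODE vM1 annotation, matched by symbol.

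The tests, their threshold and most alternatives were set before the data were examined. Those alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, a filter of at least 2 CPM in 2 libraries, a fit of only the groups compared, a replicate block, separate empty vector controls for each fusion, and leaving out each library in turn. When 1 library was left out, the lone library of its group was taken to vary like the other groups. A further 5 alternatives were chosen after seeing the data: leaving out the 5 most abundant non-coding genes, total-count scaling without those 5, thinning each library to the total of the shallowest, thinning each to the lowest count outside those 5, and removing a smooth trend on transcript length and GC content with mgcv 1.9.3. The correlation between the fusions was set beside 20 simulations in which unchanged groups shared the empty vector libraries. Figures were drawn with matplotlib 3.10.9.

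The pipeline was tested on simulated data with 200 changed genes per comparison. Of genes changed 1.5-fold, 35.8 to 46.3% were called over the 6 comparisons. The figures were 62.7 to 80.6% at a fold of 2 and 83.3 to 92.4% at a fold of 4. Between 5 and 19 unchanged genes were called per comparison, and 0 changed genes were called in the wrong direction. The 19 came with TCF3-ZNF384 over full-length ZNF384, beside 28, 54 and 59 recovered genes at folds of 1.5, 2 and 4. That is a larger share of the calls than the threshold of 0.05. The threshold was also exceeded for TCF3-ZNF384 over TAF15-ZNF384, with 18 unchanged genes beside 24, 49 and 60. TCF3-ZNF384 over the empty vector exceeded it with 15, beside 25, 46 and 61. Full-length ZNF384 over the empty vector had 8 beside 27, 45 and 58, slightly above it. TAF15-ZNF384 over the empty vector had 7 beside 31, 42 and 55, also slightly above. Only TAF15-ZNF384 over full-length ZNF384 stayed below it, with 5 beside 27, 47 and 61. A simulated list of 30 genes changed 1.5-fold was called in 6 of the 6 comparisons and an unchanged list in 0 of 6, at an unadjusted p under 0.05. With an estimated correlation the counts were also 6 and 0. The simulated genes varied independently, so this could not show false calls from genes that vary together. In the data 1308 to 5916 genes were called per comparison, far more than the 200 changed here. The recovery and the number of unchanged genes called therefore do not carry over to the data.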

Results

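Total RNA was sequenced from pre-B cells that were grown from the bone marrow of C57BL/6 mice lacking Arf, a tumour suppressor product of Cdkn2a, and transduced with lentivirus. ZNF384 is a zinc finger transcription factor whose gene is fused to TAF15, TCF3 and other genes in acute leukaemia. The 8 libraries fell into 4 groups of 2: the empty vector, full-length ZNF384, TAF15-ZNF384 and TCF3-ZNF384. Total counts per library were 28469291 and 29072409 with the empty vector and 41483660 and 20298726 with full-length ZNF384. They were 9381954 and 9963494 with TAF15-ZNF384, and 9583008 and 17876711 with TCF3-ZNF384. Of 32499 genes in the table, 12970 passed the filter on low counts and were tested. The correlation between replicates across genes was 0.977 to 0.989, where genes are not independent replicates.

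A group of 5 abundant non-coding genes, Gm26917, Rpph1, Rmrp, Gm42418 and AY036118, took a share of the counts that differed between groups. The share was 27.2 and 33.2% in the empty vector libraries, 10.9 and 12.5% with full-length ZNF384, 28.1 and 29.6% with TAF15-ZNF384 and 18.5 and 24.5% with TCF3-ZNF384. The deposited column names of the empty vector libraries lack a suffix that those of the other 6 libraries carry. Any separate preparation would coincide with that group and cannot be told apart from it by batch, because the empty vector libraries hold samples of 1 group only.

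Reads assigned to Zfp384, the mouse counterpart of ZNF384 (mm9 chromosome 6, from 124959163 to 124987883, protein coding), rose with each construct. The means were 22.8 ± 1.67 CPM (SD, n = 2) with the empty vector, 70.7 ± 27.7 with full-length ZNF384, 173 ± 15.8 with TAF15-ZNF384 and 481 ± 43.2 with TCF3-ZNF384. Over the empty vector, the log2 fold changes were 1.62 ± 0.25 (SE, adjusted p = 0.00361), 2.93 ± 0.26 (adjusted p = 0.000435) and 4.40 ± 0.27 (adjusted p = 1.34e-05). The constructs carry human sequence, whose reads map to the mouse gene only in part, so these values rank transcript levels between groups only roughly. TCF3-ZNF384 exceeded TAF15-ZNF384 by a log2 fold change of 1.47 ± 0.24 (adjusted p = 0.00772), and that call was lost without TAF15-ZNF384 replicate 2, at 1.38, and without TCF3-ZNF384 replicate 1, at 1.38. Taf15, an RNA-binding protein gene, did not pass the test over the empty vector, at 0.23, −0.11 and −0.24 with full-length ZNF384, TAF15-ZNF384 and TCF3-ZNF384. Tcf3, which encodes the E proteins E12 and E47, rose by a log2 fold change of 0.51 ± 0.11 with TCF3-ZNF384 (adjusted p = 0.00224) and by 0.40 ± 0.11 with TAF15-ZNF384 (adjusted p = 0.0267). It did not differ between the fusions, at 0.10 ± 0.11 (adjusted p = 0.629). Taf15 was lower with TAF15-ZNF384 than with full-length ZNF384, at −0.34 ± 0.12 (adjusted p = 0.0466). Neither gene therefore checked the label of its fusion. Cdkn2a rose with TCF3-ZNF384, by 0.70 ± 0.13 (adjusted p = 0.000855). It was at 59.0 to 100 CPM over the libraries. Counts per gene do not separate its products, so they neither check the lack of Arf nor show Arf.

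**Figure D1:**
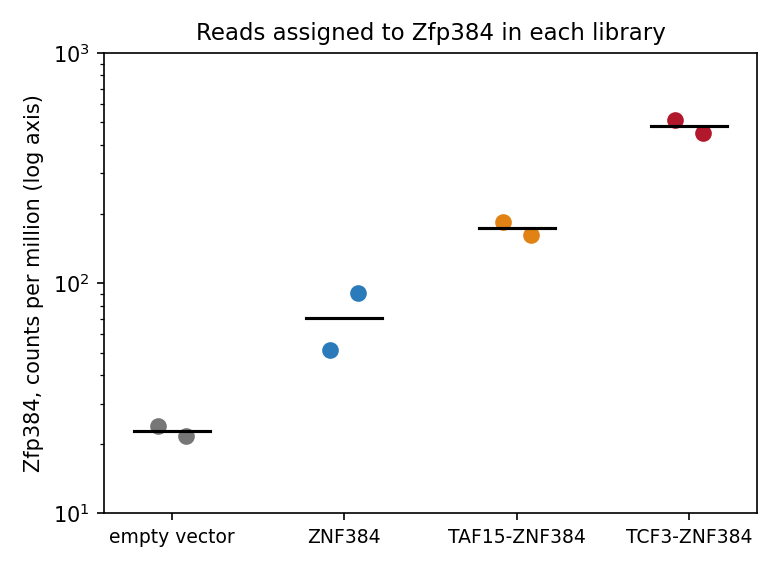
Normalised counts (CPM) assigned to Zfp384 in each library, on a log axis, by group; points are libraries and lines are group means. The means run from 22.8 with the empty vector to 481 with TCF3-ZNF384.

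The comparison of full-length ZNF384 with the empty vector asked what the unfused protein does to pre-B cells. Snai1, which encodes a transcriptional repressor (chromosome 2, from 167363695 to 167368314), was at 0.0655 ± 0.0927 CPM (SD, n = 2) against 6.90 ± 2.79, a ratio of 152 with an interval of 51.7 to 742 (adjusted p = 1.48e-05). The Notch ligand gene Dll1 (chromosome 17, from 15504318 to 15513836) fell by 4.79 ± 0.48 on the log2 scale (adjusted p = 2.01e-05). Pfkl, the liver-type phosphofructokinase of glycolysis (chromosome 10, from 77449692 to 77472828), rose from 102 ± 0.158 to 366 ± 54.2 CPM (n = 2), a 3.60-fold change.

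Among the lists, the immediate early genes fell furthest, with a median log2 fold change of −2.45 that was the same with Ier3, at 0 with full-length ZNF384, at its bound. Of 20 tested members 19 fell, and 20 fell adjusted over the list alone (adjusted p = 2.12e-30; adjusted p = 0.145 with an estimated correlation). Examples were the heat shock gene Hspa1b, at −3.43 ± 0.32, whose sequence is nearly identical to that of Hspa1a, and the mRNA decay factor gene Zfp36, at −1.24 ± 0.15. The share of the 5 non-coding genes, 10.9 and 12.5% against 27.2 and 33.2%, was lower in the same libraries. NF-kB and inflammatory genes fell as a list, with 8 of 13 members lower, or 9 adjusted over the list alone (median −0.88, or −0.98 with Ier3 at its bound and without Il10; adjusted p = 4.71e-12; adjusted p = 0.110 with an estimated correlation). They included the NF-kB inhibitor gene Nfkbia (−1.85 ± 0.13) and the subunit genes Nfkb2 (−1.69 ± 0.14) and Relb (−2.31 ± 0.23). In the unfolded protein and integrated stress response list 13 of 21 members fell and 3 rose, or 13 and 5 adjusted over the list alone (median −0.76, adjusted p = 5.07e-08; adjusted p = 0.110 with an estimated correlation). The stress-induced Ddit3 (−2.74 ± 0.15) and Trib3 (−1.91 ± 0.13) fell, whereas Pdia4 (0.71 ± 0.11) and Sdf2l1 (0.84 ± 0.13), which act in protein folding in the endoplasmic reticulum, rose. Of 25 p53 pathway members 10 fell and 1 rose, with the same counts adjusted over the list alone (median −0.32, adjusted p = 3.27e-05; adjusted p = 0.238 with an estimated correlation). The cell death gene Bbc3 was at −1.60 ± 0.13. Of 30 replication-dependent histone genes 14 fell and 2 rose, or 16 and 4 adjusted over the list alone (median −0.30, adjusted p = 0.00013; adjusted p = 0.633 with an estimated correlation).

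Glycolysis and hypoxia genes rose as a list, with 16 of 25 members higher and 1 lower, the same counts as adjusted over the list alone (median 0.77, adjusted p = 4.57e-17; adjusted p = 0.110 with an estimated correlation). Besides Pfkl they included Bnip3 (1.60 ± 0.12), a hypoxia-induced mitophagy gene, and Pdk1 (1.43 ± 0.11), a pyruvate dehydrogenase kinase gene. Cholesterol synthesis genes rose in 14 of 17 members, and 15 rose and 1 fell adjusted over the list alone (median 0.79, adjusted p = 4.57e-17; adjusted p = 0.110 with an estimated correlation). An example was Stard4, at 0.87 ± 0.09. MYC targets rose in 10 of 27 members, also adjusted over the list alone (median 0.24, adjusted p = 0.00026; adjusted p = 0.633 with an estimated correlation). Of 26 G2 and M phase genes 11 rose, or 14 adjusted over the list alone (median 0.29, adjusted p = 0.000201; adjusted p = 0.633 with an estimated correlation). Oxidative phosphorylation rose as a list with 5 of 33 members higher, or 2 adjusted over the list alone (median 0.17, adjusted p = 0.0442; adjusted p = 0.708 with an estimated correlation). Pre-B cell receptor signalling genes fell in 6 of 21 members and rose in 3, also adjusted over the list alone (median −0.22, adjusted p = 0.0197; adjusted p = 0.633 with an estimated correlation). The repressor gene Bcl6 fell by 1.29 ± 0.12 and the kinase gene Btk by 0.95 ± 0.11 on the log2 scale. Without full-length ZNF384 replicate 1 the calls ended for MYC targets (median 0.03, adjusted p = 0.222, range 2.22e-10 to 0.633 over the alternatives), G2 and M phase (0.13, adjusted p = 0.0609, range 3.00e-08 to 0.633), oxidative phosphorylation (0.07) and pre-B cell receptor signalling (−0.09). Without replicate 2 of that group the medians of MYC targets, pre-B cell receptor signalling and glycolysis were 0.46, −0.42 and 0.51, the stress response median was −0.50 without empty vector replicate 1, and the oxidative phosphorylation call also ended without empty vector replicate 2, at 0.15. That call ended further with at least 2 CPM in 2 libraries (0.15), in a fit of only these 2 groups (0.14), after the length and GC correction (0.19) and at equal counts outside the 5 non-coding genes (0.19). The pre-B cell receptor call ended with at least 2 CPM in 2 libraries (−0.21), and the histone median was −0.16 after the length and GC correction.

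The lists of B lineage, E protein and Id network, and IL-7 signalling genes were not called. Of 32 B lineage genes 5 rose and 5 fell, or 7 and 6 adjusted over the list alone. The gene of the DNA polymerase TdT, Dntt (chromosome 19, from 41103765 to 41134013), rose 4.79-fold and Cd22, an inhibitory receptor gene, rose by 1.24 ± 0.18. In all, 2675 of 12970 genes changed, 1395 up and 1280 down. Of these, 138 rose and 470 fell at least 2-fold. The number was 1583 without empty vector replicate 1 and 1064 without empty vector replicate 2.

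**Figure D2:**
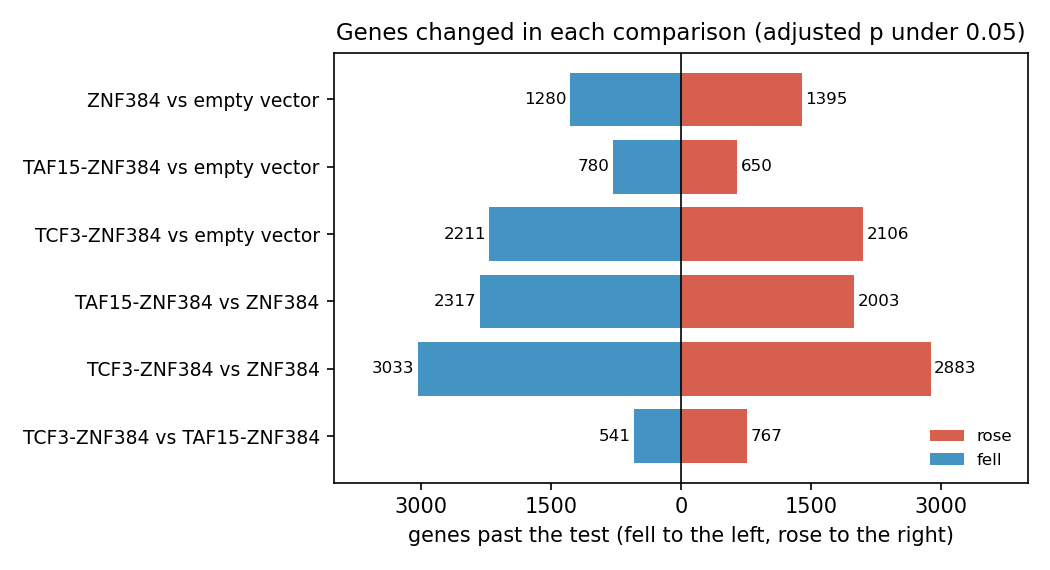
Number of genes past the test in each of the 6 comparisons; bars to the right count genes that rose and bars to the left genes that fell in the first group named. The 2 comparisons of a fusion with full-length ZNF384 have 4320 and 5916 changed genes.

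The comparison of TAF15-ZNF384 with the empty vector asked which genes this fusion changes. Rag1, which encodes a subunit of the V(D)J recombinase (chromosome 2, from 101478439 to 101489658), rose from 0.375 ± 0.245 to 7.97 ± 1.89 CPM (SD, n = 2), a 20.9-fold change (adjusted p = 3.25e-06). Igdcc3, which encodes a cell surface protein of the immunoglobulin superfamily (chromosome 9, from 64988961 to 65033664), rose 79.5-fold, to 8.37 ± 0.162 CPM (adjusted p = 2.07e-07). The Y-box protein gene Ybx2 (chromosome 11, from 69749298 to 69755107) rose 11.4-fold, to 9.34 ± 1.55 CPM. Gprin3 (chromosome 6, from 59302455 to 59376284) fell from a mean of 49.0 ± 5.98 CPM, with a log2 fold change of −2.45 ± 0.13 (adjusted p = 1.14e-07). Tnfsf11, which encodes the cytokine RANKL (chromosome 14, from 78677252 to 78707850), fell by 1.80 ± 0.19 on the log2 scale.

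Of the genes linked to ZNF384-rearranged leukaemia, a list drawn from knowledge of the disease and not from these samples, 4 of 7 tested members rose, also adjusted over the list alone (median 0.82, adjusted p = 0.00132, and adjusted p = 0.274 with an estimated correlation). The list's other members were not tested. The expression filter keeps a gene expressed in a single group. Clcf1 was at 0.508 and 0.282 CPM in the empty vector libraries and 0.367 and 0.175 with full-length ZNF384. A member low in the controls could thus be tested only if a fusion raised it, so the share that rose is not that of the whole list. The cytokine gene Clcf1 (chromosome 19, from 4214238 to 4223490) rose 10.7-fold to 4.29 ± 0.538 CPM (n = 2), and Il2ra, the interleukin-2 receptor alpha chain gene, rose by 1.51 ± 0.25, a call lost without TAF15-ZNF384 replicate 1, at 1.35. E protein and Id network genes rose as a list, with 8 of 23 members higher and 2 lower, or 10 and 4 adjusted over the list alone (median 0.19, adjusted p = 0.00106; adjusted p = 0.586 with an estimated correlation). The Notch target Hes1 was at 0.95 ± 0.13. B lineage genes also rose as a list, with 9 of 32 members higher and 4 lower, or 12 and 6 adjusted over the list alone (median 0.09, adjusted p = 0.0163; adjusted p = 0.684 with an estimated correlation). Besides Rag1 the risers included Cd38 (1.62 ± 0.24) and Dntt (2.84 ± 0.36), whereas the kinase genes Blk (−1.18 ± 0.10) and Btk (−1.02 ± 0.12) fell. The B lineage list and the E protein and Id network list share members, among them Rag1 and Rag2, so their calls are not independent. Matrix genes rose in 4 of 11 members, and 4 rose and 1 fell adjusted over the list alone (median 0.71, adjusted p = 0.00141; adjusted p = 0.586 with an estimated correlation). They included the laminin gene Lama5 (1.69 ± 0.24) and the collagenase gene Mmp13 (1.87 ± 0.22).

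Ribosomal protein genes fell together, in 26 of 42 members, or 32 adjusted over the list alone (median −0.60, adjusted p = 1.33e-20; adjusted p = 0.404 with an estimated correlation). Examples were Rpsa (−0.89 ± 0.13), Rpl23 (−0.79 ± 0.13) and Rplp0 (−0.65 ± 0.10), genes with pseudogene copies in the genome. In the unfolded protein and integrated stress response list 9 of 21 members fell, and 10 fell and 1 rose adjusted over the list alone (median −0.35, adjusted p = 1.16e-07; adjusted p = 0.274 with an estimated correlation). Those that fell were led by the integrated stress response gene Trib3 (−1.82 ± 0.13) and the amino acid synthesis genes Asns (−1.08 ± 0.10) and Phgdh (−0.86 ± 0.11). MYC targets fell in 3 of 27 members, or 14 adjusted over the list alone (median −0.31, adjusted p = 0.000133; adjusted p = 0.684 with an estimated correlation). Replication-dependent histones fell in 8 of 30 members, or 10 adjusted over the list alone (median −0.24, adjusted p = 0.000379; adjusted p = 0.684 with an estimated correlation). Cholesterol synthesis genes fell in 4 of 17 members, or 5 adjusted over the list alone (median −0.19, adjusted p = 0.00819; adjusted p = 0.684 with an estimated correlation). The immediate early list was not called, with a median of 0.08 (adjusted p = 0.605).

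In all, 1430 of 12970 genes changed with TAF15-ZNF384, 650 up and 780 down, of which 190 rose and 143 fell at least 2-fold. The number was 549 and 686 without empty vector replicate 1 or 2, 404 and 536 without TAF15-ZNF384 replicate 1 or 2, and 2746 when only these 2 groups were fitted. Without empty vector replicate 2 the calls ended for B lineage genes (median 0.07, adjusted p = 0.0678, range 0.000451 to 0.684 over the alternatives) and cholesterol synthesis (−0.10, adjusted p = 0.285, range 6.23e-05 to 0.684, against −0.31 without replicate 1), the B lineage median was 0.15 without TAF15-ZNF384 replicate 1, and the matrix median was 0.40 and 1.32 without TAF15-ZNF384 replicate 1 or 2. Without the filter on low counts the calls ended for the leukaemia list (median 0.25) and matrix genes (0.12), and the matrix median was 1.33 with at least 2 CPM in 2 libraries and 1.21 and 1.09 in the 2 thinned fits. Total-count scaling gave medians of 0.20 for B lineage, 0.30 for E protein, −0.20 for MYC target, −0.13 for histone and −0.08 for cholesterol synthesis genes, and the length and GC correction gave 0.13 for B lineage and −0.15 for histone genes.

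The comparison of TCF3-ZNF384 with the empty vector asked the same of the second fusion. Rag1 rose from 0.375 ± 0.245 to 61.3 ± 8.79 CPM (SD, n = 2), a log2 fold change of 7.32 ± 0.26 (adjusted p = 3.83e-10), and Igdcc3 rose to 31.3 ± 2.00 CPM, by 8.22 ± 0.30. The ion channel gene Trpa1 (chromosome 1, from 14862729 to 14908943) rose 113-fold to 18.7 ± 2.88 CPM (adjusted p = 6.82e-09). H60b, an NKG2D ligand gene of a family of similar sequences (chromosome 10, from 21878392 to 22008655), had 0 counts in both empty vector libraries and was at least 98.1-fold higher, at 6.23 ± 2.12 CPM (adjusted p = 1.48e-05). Gprin3 fell to 5.04 ± 0.102 CPM, by 3.28 ± 0.13 on the log2 scale (adjusted p = 9.12e-10). The neuropeptide receptor gene Vipr1 (chromosome 9, from 121551834 to 121582072) fell by 3.30 ± 0.31 and Tnfsf11 by 2.89 ± 0.20.

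Of the genes linked to ZNF384-rearranged leukaemia 6 of 7 tested members rose, also adjusted over the list alone (median 2.91, adjusted p = 1.05e-06, and adjusted p = 0.0887 with an estimated correlation). The limit on which members were tested holds here too, and the median was 0.49 without the filter on low counts. The receptor tyrosine kinase gene Flt3 (chromosome 5, from 148142317 to 148212065) rose 7.51-fold to 19.1 ± 0.994 CPM (n = 2, adjusted p = 5.82e-08). Il2ra (chromosome 2, from 11564419 to 11614818) rose 14.4-fold to 168 ± 5.71 CPM and Clcf1 rose 20.3-fold to 8.05 ± 3.31 CPM. The B lineage list was not called: 10 of 32 members rose and 9 fell, the same counts as adjusted over the list alone. With Rag1 rose Dntt (4.34 ± 0.33). The surrogate light chain gene Vpreb2 (−1.86 ± 0.14) and the kinase genes Blk (−1.90 ± 0.11) and Btk (−1.54 ± 0.12) fell. E protein and Id network genes went both ways without a call, with 8 of 23 higher and 6 lower, or 9 and 6 adjusted over the list alone, among them the E protein gene Tcf4 (1.99 ± 0.13) and the repressor gene Gfi1 (−1.57 ± 0.13). IL-7 and JAK-STAT signalling was not called either, with 3 of 22 members higher and 6 lower, also adjusted over the list alone. Bcl2, a survival gene, fell by 1.69 ± 0.11 on the log2 scale.

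Ribosomal protein genes fell in 38 of 42 members, or 39 adjusted over the list alone (median −0.89, adjusted p = 1.07e-15; adjusted p = 0.467 with an estimated correlation). Replication-dependent histones fell in 28 of 30, also adjusted over the list alone (median −0.81, adjusted p = 1.45e-20; adjusted p = 0.455 with an estimated correlation). Examples were Rplp0 (−0.91 ± 0.10), Rpl12 (−1.02 ± 0.12) and Hist1h2ac (−1.17 ± 0.10). MYC targets fell in 25 of 27 members, also adjusted over the list alone (median −0.61, adjusted p = 1.76e-08; adjusted p = 0.612 with an estimated correlation). The spermidine synthase gene Srm was at −1.24 ± 0.15. G2 and M phase genes fell in 21 of 26 members, or 23 adjusted over the list alone (median −0.44, adjusted p = 2.34e-05; adjusted p = 0.658 with an estimated correlation). S phase genes fell in 14 of 26, or 18 adjusted over the list alone (median −0.39, adjusted p = 0.00176; adjusted p = 0.658 with an estimated correlation). The replication helicase gene Mcm5 fell by 0.77 ± 0.12 on the log2 scale. In the unfolded protein and integrated stress response list 13 of 21 members fell, or 14 adjusted over the list alone (median −0.75, adjusted p = 6.79e-11; adjusted p = 0.0887 with an estimated correlation), led again by Trib3 (−2.44 ± 0.14), Asns (−1.65 ± 0.11) and Phgdh (−1.29 ± 0.11). This list fell over the empty vector with each construct. The mean log2 CPM of its members was 5.84 and 5.85 with the empty vector and 5.05 and 5.26 with full-length ZNF384. It was 5.42 and 5.48 with TAF15-ZNF384 and 4.98 and 5.07 with TCF3-ZNF384. Separate preparation of the empty vector libraries could give a fall common to the constructs and cannot be told apart from them.

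Glycolysis and hypoxia genes fell in 10 of 25 members and rose in 4, or 10 and 5 adjusted over the list alone (median −0.25, adjusted p = 0.0235; adjusted p = 0.658 with an estimated correlation). The angiogenic factor gene Vegfa was at −1.50 ± 0.13 and Pdk1 at 0.70 ± 0.11. Cholesterol synthesis genes fell in 9 of 17 members and rose in 1, or 11 and 1 adjusted over the list alone (median −0.43, adjusted p = 0.0163; adjusted p = 0.658 with an estimated correlation). Oxidative phosphorylation genes fell in 9 of 33 members, also adjusted over the list alone (median −0.21, adjusted p = 0.0235; adjusted p = 0.658 with an estimated correlation). In all, 4317 of 12970 genes changed, 2106 up and 2211 down. Of these, 692 rose and 445 fell at least 2-fold. The number was 2855 and 2827 without empty vector replicate 1 or 2 and 2630 and 2501 without TCF3-ZNF384 replicate 1 or 2. Calls ended for glycolysis without TCF3-ZNF384 replicate 1 (median −0.19, adjusted p = 0.0540, range 0.00395 to 0.658 over the alternatives; −0.42 without replicate 2), for cholesterol synthesis without empty vector replicate 2 (−0.28, adjusted p = 0.151, range 0.000364 to 0.658), and for oxidative phosphorylation without empty vector replicate 1 (adjusted p = 0.0632, range 0.000199 to 0.658). The oxidative phosphorylation call also ended after the length and GC correction and with total-count scaling, at −0.07 in both. The leukaemia list median was 0.49 without the filter on low counts and 1.71 and 1.69 in the 2 thinned fits. Total-count scaling gave −0.25 for S phase and −0.12 for glycolysis, and thinning to equal counts outside the 5 non-coding genes gave −0.39 for glycolysis.

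**Figure D3:**
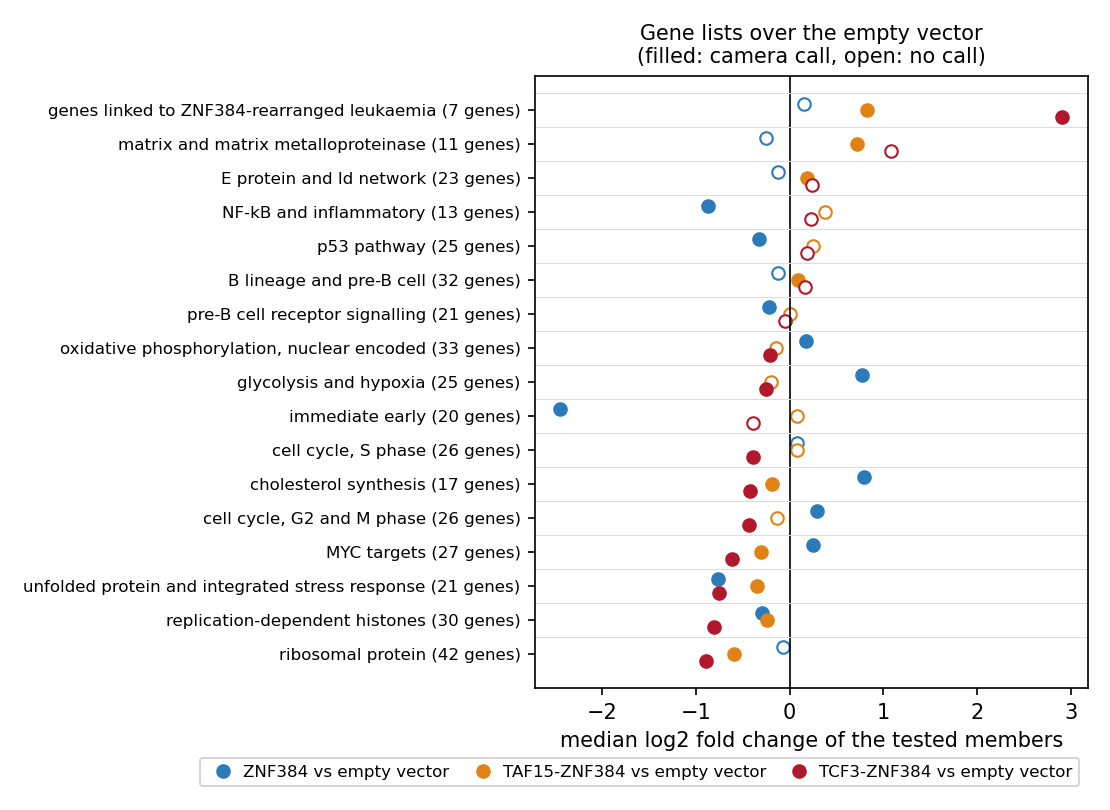
Median log2 fold change of the tested members of each gene list called in at least 1 comparison with the empty vector, for the 3 constructs; filled points are calls by camera with the preset correlation and open points are not called. Immediate early genes lie at −2.45 with full-length ZNF384 and ribosomal protein genes at −0.60 and −0.89 with the fusions.

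**Figure D4:**
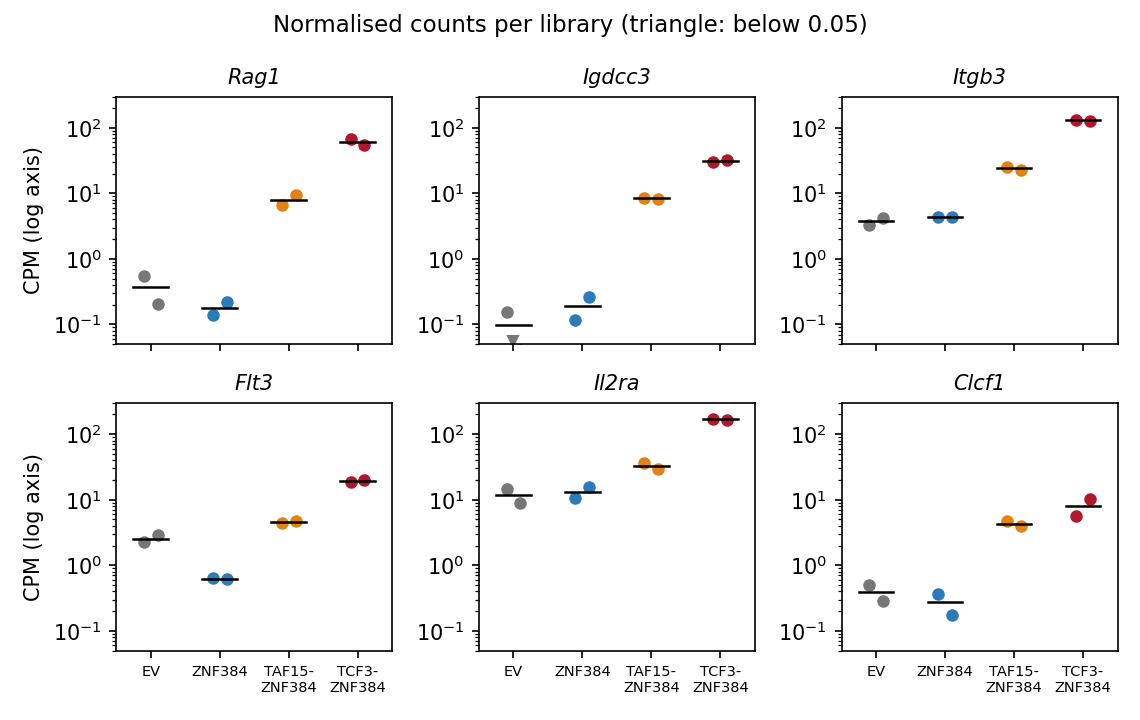
Normalised counts (CPM) in each library for Rag1, Igdcc3, Itgb3, Flt3, Il2ra and Clcf1, on log axes; points are libraries, lines are group means and a triangle marks a value below 0.05. Rag1 means are 0.375 with the empty vector, 7.97 with TAF15-ZNF384 and 61.3 with TCF3-ZNF384.

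The comparison of TAF15-ZNF384 with full-length ZNF384 asked what the fusion adds to or takes from the unfused protein. Rag1 was 46.4-fold higher with the fusion, at 7.97 ± 1.89 against 0.178 ± 0.0572 CPM (SD, n = 2, adjusted p = 3.11e-07), and Igdcc3 was 48.5-fold higher. Snai1 was at 5.74 ± 0.491 CPM against 0.0655 ± 0.0927, a ratio of 127 with an interval of 42.4 to 626. Gimap7, which encodes a GTPase of the immunity-associated family (chromosome 6, from 48668620 to 48674635), fell by 4.49 ± 0.47 on the log2 scale (adjusted p = 1.40e-05), and Gprin3 by 3.17 ± 0.13 (adjusted p = 9.61e-09).

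Immediate early genes rose in 19 of 20 members, also adjusted over the list alone (median 2.40, unchanged with Ier3 at its bound; adjusted p = 1.01e-21; adjusted p = 0.237 with an estimated correlation). The share of the 5 non-coding genes, 28.1 and 29.6% against 10.9 and 12.5%, differed between the same libraries. NF-kB and inflammatory genes rose in 8 of 13 members and fell in 1, or 10 and 1 adjusted over the list alone (median 1.56, or 1.15 with Ier3 at its bound and without Il10; adjusted p = 2.96e-10; adjusted p = 0.237 with an estimated correlation). Nfkbia was at 2.02 ± 0.14. Of 25 p53 pathway members 14 rose and 1 fell, or 15 and 1 adjusted over the list alone (median 0.50, adjusted p = 1.36e-06; adjusted p = 0.237 with an estimated correlation). Bbc3 was at 1.52 ± 0.13. E protein and Id network genes rose in 10 of 23 members and fell in 3, also adjusted over the list alone (median 0.21, or 0.35 without full-length ZNF384 replicate 2; adjusted p = 8.57e-05; adjusted p = 0.367 with an estimated correlation). Of the genes linked to ZNF384-rearranged leukaemia 4 of 7 rose and 1 fell, also adjusted over the list alone (median 1.25, adjusted p = 0.0208; adjusted p = 0.256 with an estimated correlation). Flt3 was at 2.82 ± 0.26 and Cd52, a lymphocyte surface glycoprotein gene, at −1.23 ± 0.12. B lineage genes rose in 11 of 32 members and fell in 7, or 12 and 8 adjusted over the list alone (median 0.20, adjusted p = 0.0169; adjusted p = 0.680 with an estimated correlation). That list shares members with the E protein and Id network list, among them Rag1 and Rag2. Matrix genes rose in 7 of 11 with 2 lower, or 8 and 2 adjusted over the list alone (median 1.39, adjusted p = 0.0186; adjusted p = 0.594 with an estimated correlation).

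Cholesterol synthesis genes fell in 14 of 17 members and rose in 1, or 15 and 1 adjusted over the list alone (median −1.15, adjusted p = 1.44e-17; adjusted p = 0.227 with an estimated correlation). Glycolysis and hypoxia genes fell in 17 of 25, or 19 adjusted over the list alone (median −0.89, adjusted p = 4.10e-16; adjusted p = 0.227 with an estimated correlation). Pfkl was at −1.93 ± 0.12. Ribosomal protein genes fell in 29 of 42 members, or 36 adjusted over the list alone (median −0.61, adjusted p = 1.35e-09; adjusted p = 0.406 with an estimated correlation). MYC targets fell in 20 of 27, or 23 adjusted over the list alone (median −0.57, adjusted p = 3.36e-09; adjusted p = 0.423 with an estimated correlation). G2 and M phase genes fell in 18 of 26 members and rose in 1, or 23 and 1 adjusted over the list alone (median −0.41, adjusted p = 6.71e-06; adjusted p = 0.594 with an estimated correlation). Oxidative phosphorylation genes fell in 14 of 33 members, and 17 fell and 1 rose adjusted over the list alone (median −0.29, adjusted p = 0.00285; adjusted p = 0.594 with an estimated correlation). In all, 4320 genes changed, 2003 up and 2317 down, against 2158 and 2736 without TAF15-ZNF384 replicate 1 or 2. Without full-length ZNF384 replicate 1 the calls ended for B lineage genes (median 0.12) and for the leukaemia list (1.11), which also ended without replicate 2 of that group (1.21), and the G2 and M phase median was −0.27, while the matrix median was 0.76 without TAF15-ZNF384 replicate 1. The matrix call ended with at least 2 CPM in 2 libraries (0.84), without the filter on low counts (0.53), with only these 2 groups (0.83), after the length and GC correction (1.34) and with total-count scaling (1.55). The leukaemia call ended with limma-voom (1.25) and without the filter (0.61), and the oxidative phosphorylation call after the length and GC correction (−0.15). The NF-kB median was 0.68 without the filter, and total-count scaling gave 0.34 for B lineage, 0.34 for E protein, −0.27 for G2 and M phase and −0.14 for oxidative phosphorylation genes.

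The comparison of TCF3-ZNF384 with full-length ZNF384 asked the same of the other fusion. Rag1 was higher by a log2 fold change of 8.47 ± 0.28 (adjusted p = 1.37e-10, n = 2), Trpa1 by 8.13 ± 0.37 and Flt3 by 4.91 ± 0.22. Gprin3 fell by 3.99 ± 0.13 on the log2 scale (adjusted p = 1.37e-10), and Gimap7 by 3.13 ± 0.36. Bcl2 fell from 371 ± 24.9 to 51.0 ± 3.27 CPM, by 2.87 ± 0.11 on the log2 scale.

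Ribosomal protein genes fell in 42 of 42 members, also adjusted over the list alone (median −0.75, adjusted p = 4.21e-11; adjusted p = 0.376 with an estimated correlation). MYC targets fell in 26 of 27, or 27 adjusted over the list alone (median −0.93, adjusted p = 3.28e-13; adjusted p = 0.376 with an estimated correlation). G2 and M phase genes fell in 25 of 26, also adjusted over the list alone (median −0.75, adjusted p = 7.03e-10; adjusted p = 0.376 with an estimated correlation). Histones fell in 28 of 30 members, also adjusted over the list alone (median −0.58, adjusted p = 4.03e-08; adjusted p = 0.376 with an estimated correlation). S phase genes fell in 17 of 26, or 18 adjusted over the list alone (median −0.45, adjusted p = 0.00280; adjusted p = 0.611 with an estimated correlation). Glycolysis and hypoxia genes fell in 19 of 25 members and rose in 1, also adjusted over the list alone (median −1.04, adjusted p = 2.37e-13; adjusted p = 0.237 with an estimated correlation). Cholesterol synthesis genes fell in 15 of 17, also adjusted over the list alone (median −1.22, adjusted p = 2.37e-13; adjusted p = 0.237 with an estimated correlation). Pfkl was at −2.09 ± 0.12. Oxidative phosphorylation genes fell in 19 of 33 members, or 20 adjusted over the list alone (median −0.34, adjusted p = 0.000436; adjusted p = 0.456 with an estimated correlation). In the unfolded protein and integrated stress response list 11 of 21 members fell and 5 rose, or 11 and 7 adjusted over the list alone (median −0.47, adjusted p = 0.0442; adjusted p = 0.376 with an estimated correlation). IL-7 and JAK-STAT signalling fell by the test with 6 of 22 members lower and 1 higher, also adjusted over the list alone, although its median was 0.11 and its mean −0.11 (adjusted p = 0.0442; adjusted p = 0.376 with an estimated correlation).

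Immediate early genes rose in 19 of 20 members, also adjusted over the list alone (median 2.23, unchanged with Ier3 at its bound; adjusted p = 8.39e-10; adjusted p = 0.376 with an estimated correlation), in libraries where the 5 non-coding genes took 18.5 and 24.5% against 10.9 and 12.5%. NF-kB and inflammatory genes rose in 10 of 13 members and fell in 2, or 10 and 3 adjusted over the list alone (median 1.48, unchanged with Ier3 and Il10 at their bounds; adjusted p = 6.84e-07; adjusted p = 0.376 with an estimated correlation). Of 25 p53 pathway members 15 rose and 1 fell, or 16 and 1 adjusted over the list alone (median 0.47, adjusted p = 0.00101; adjusted p = 0.376 with an estimated correlation). The E protein and Id network rose in 12 of 23 members and fell in 6, also adjusted over the list alone (median 0.43, adjusted p = 0.00505; adjusted p = 0.376 with an estimated correlation). The leukaemia list rose in 4 of 7 with 1 lower, also adjusted over the list alone (median 1.78, or 2.71 without full-length ZNF384 replicate 1; adjusted p = 3.04e-05; adjusted p = 0.237 with an estimated correlation). In all, 5916 genes changed, 2883 up and 3033 down, against 3866 without TCF3-ZNF384 replicate 2. The S phase call ended without full-length ZNF384 replicate 1 (median −0.22, adjusted p = 0.0586, range 4.22e-06 to 0.611 over the alternatives), the stress response call ended without full-length ZNF384 replicate 2 (−0.19) and without TCF3-ZNF384 replicate 1 (−0.43) or 2 (−0.35), and the IL-7 call ended without full-length ZNF384 replicate 2 (0.18) and without TCF3-ZNF384 replicate 1 (0.14). The IL-7 call also ended with at least 2 CPM in 2 libraries (0.14), limma-voom (0.12), no filter (0.15), only these 2 groups (0.13), a replicate block (0.11) and in the 2 thinned fits (0.12 and 0.13), and its median was −0.02 without full-length ZNF384 replicate 1, −0.04 without TCF3-ZNF384 replicate 2, 0.01 after the length and GC correction and 0.28 with total-count scaling. The stress response call ended with limma-voom (−0.47), only these 2 groups (−0.49), a replicate block (−0.47) and the length and GC correction (−0.46), the E protein call with limma-voom (0.31) and the oxidative phosphorylation call after the length and GC correction (−0.12). Total-count scaling gave −0.28 for S phase, −0.17 for oxidative phosphorylation and −0.30 for the stress response, and at least 2 CPM in 2 libraries gave 3.73 for the leukaemia list and 0.27 for E protein genes.

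The comparison of the fusions with each other asked where their effects differ. Both raised Rag1, and TCF3-ZNF384 raised it further, by 2.94 ± 0.19 over TAF15-ZNF384 (adjusted p = 6.45e-07). H60b had 0 counts in both TAF15-ZNF384 libraries and was at least 36.3-fold higher with TCF3-ZNF384. Cubn, which encodes the endocytic receptor cubilin (chromosome 2, from 13197965 to 13413551), rose 25.5-fold to 9.72 ± 0.725 CPM (SD, n = 2), and the integrin gene Itgb7 (chromosome 15, from 102046426 to 102062366) rose 18.4-fold to 5.07 ± 0.772 CPM. Lgr5, an R-spondin receptor gene (chromosome 10, from 114887367 to 115024836), fell by 2.08 ± 0.25 on the log2 scale (adjusted p = 0.000129), and Ankrd45 (chromosome 1, from 163072822 to 163099237) fell by 2.47 ± 0.38.

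Histone genes fell in 28 of 30 members, or 30 adjusted over the list alone (median −0.60, adjusted p = 5.00e-29; adjusted p = 0.280 with an estimated correlation). S phase genes fell in 12 of 26, or 20 adjusted over the list alone (median −0.41, adjusted p = 2.86e-10; adjusted p = 0.841 with an estimated correlation). Uhrf1, a DNA methylation maintenance gene, was at −0.66 ± 0.10. G2 and M phase genes fell in 5 of 26 members, or 12 adjusted over the list alone (median −0.29, adjusted p = 8.20e-06; adjusted p = 0.841 with an estimated correlation). MYC targets fell in 6 of 27, or 12 adjusted over the list alone (median −0.33, adjusted p = 4.67e-06; adjusted p = 0.841 with an estimated correlation). In the unfolded protein and integrated stress response list 8 of 21 members fell, or 12 adjusted over the list alone (median −0.41, adjusted p = 2.91e-06; adjusted p = 0.261 with an estimated correlation). The serine pathway gene Shmt2 was at −0.66 ± 0.12. The leukaemia list rose in 3 of 7 members, or 4 adjusted over the list alone (median 0.93, adjusted p = 1.42e-05; adjusted p = 0.233 with an estimated correlation). Il2ra was at 2.34 ± 0.24 and Flt3 at 2.09 ± 0.19. The ribosomal protein list was lower by camera with 1 of 42 members past the edgeR test, or 0 adjusted over the list alone (median −0.23, adjusted p = 0.00128; adjusted p = 0.841 with an estimated correlation). Of its members 8 were lower at an unadjusted p under 0.05, and 2 passed with DESeq2 and 0 with limma-voom. The immediate early list was lower by camera with 0 of 20 members past the edgeR test, also adjusted over the list alone (median −0.41, adjusted p = 0.0303; adjusted p = 0.841 with an estimated correlation). Of its members 6 had an unadjusted p under 0.05, 5 of them lower, and 1 passed with DESeq2 and 3 with limma-voom. In all, 1308 genes changed, 767 up and 541 down, against 579 and 371 without TAF15-ZNF384 replicate 1 or 2, 506 and 646 without TCF3-ZNF384 replicate 1 or 2, and 2548 when only these 2 groups were fitted. The immediate early call ended without TAF15-ZNF384 replicate 1 (median −0.21) and without TCF3-ZNF384 replicate 1 (−0.16), and the median was −0.69 without TCF3-ZNF384 replicate 2. It also ended with at least 2 CPM in 2 libraries (−0.42), only these 2 groups (−0.40), the length and GC correction (−0.39) and in the 2 thinned fits (−0.40 and −0.41), and the ribosomal protein call ended after the length and GC correction (−0.14).

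The last question was which genes both fusions changed in the same direction over both controls. Over the empty vector 549 genes rose with both fusions and 658 fell with both. Independent lists of these sizes would share 106 genes that rose and 133 that fell. The 2 comparisons share the empty vector libraries. In 20 simulations of unchanged groups that shared them at most 2 genes were called with both fusions in either direction. With nothing changed hardly any gene can be called, so that value does not bound the overlap of long lists. Of the 1207 genes changed by both fusions in the same direction, 358 also rose and 459 also fell in both over full-length ZNF384, 817 in all or 67.7%. Of the 817, full-length ZNF384 over the empty vector changed 50 the same way, Zfp384 among them, and 148 the opposite way, and 619 did not pass that test. Over the empty vector 145 genes rose and 148 fell with all 3 constructs. Besides Rag1, Igdcc3 and Ybx2, the shared risers with the largest smallest change included the integrin gene Itgb3 (chromosome 11, from 104469370 to 104531790), whose means were 3.76 ± 0.671 CPM with the empty vector, 4.35 ± 0.0382 with full-length ZNF384, 24.0 ± 1.91 with TAF15-ZNF384 and 129.9 ± 2.50 with TCF3-ZNF384 (SD, n = 2). Scube3, a secreted protein gene (chromosome 17, from 28279261 to 28311797), rose by 2.59 ± 0.25 and 3.52 ± 0.25 with TAF15-ZNF384 and TCF3-ZNF384 over the empty vector. Shared genes that fell included Gprin3, Tnfsf11 and Padi2, which encodes an enzyme that converts arginine to citrulline in proteins. The count of 817 was 354 and 433 without empty vector replicate 1 or 2, 1638 without full-length ZNF384 replicate 2, 224 and 346 without TAF15-ZNF384 replicate 1 or 2, and 521 without TCF3-ZNF384 replicate 2.

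Across the 12970 tested genes, which are not independent replicates, the log2 fold changes of the fusions over the empty vector had a Pearson correlation of 0.73 and a Spearman correlation of 0.68. Groups simulated without change that shared the empty vector libraries gave a mean of 0.36 and a maximum of 0.39. The correlation of full-length ZNF384 with TAF15-ZNF384 was 0.10, and with TCF3-ZNF384 0.13, where the simulations averaged 0.40 and 0.45. Changes that are not shared lower a correlation, so values below the simulations do not show less agreement than unchanged groups. The covariance with TAF15-ZNF384 was 0.0515, near the simulated mean of 0.0588. With TCF3-ZNF384 it was 0.0859, above the simulated mean of 0.0581 and maximum of 0.0632. Between the fusions it was 0.460, against a simulated maximum of 0.0682. Without TAF15-ZNF384 replicate 1 the correlation of the fusions was 0.48. Total-count scaling without the 5 non-coding genes, chosen after seeing the data, gave a median log2 fold change over all genes of 0.12 with TAF15-ZNF384 and 0.15 with TCF3-ZNF384 over the empty vector, and of 0.12 and 0.18 over full-length ZNF384. The share of changed genes that rose was then 67.1 and 67.6% over the empty vector, against 45.5 and 48.8% in the main fit, and 65.0 and 65.6% over full-length ZNF384, against 46.4 and 48.7%. The set shared over both controls then held 562 genes that rose and 270 that fell, against 358 and 459, so how many genes rose or fell is relative to that choice.

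**Figure D5:**
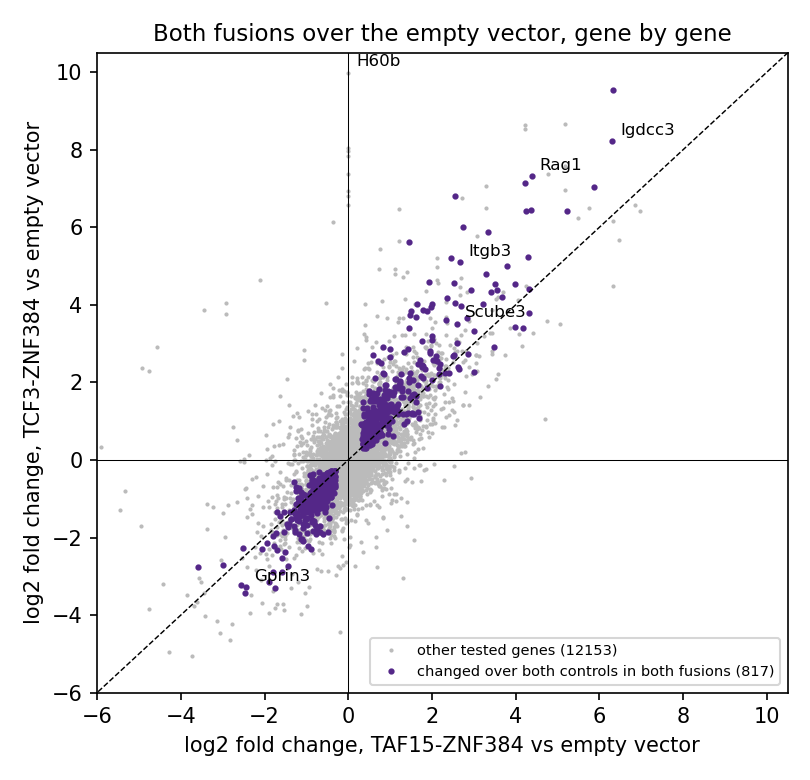
Fitted log2 fold change over the empty vector of each of 12970 tested genes with TAF15-ZNF384 (horizontal) and TCF3-ZNF384 (vertical); the 817 genes changed in both fusions over both controls are coloured and the dashed line marks equal change. The correlation across genes is 0.73, and values of genes at 0 counts in a group, such as H60b, depend on the prior count of the fit.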

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

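The tests with total-count scaling, thinning, the length and GC correction, the spread between replicates, the pseudogenes and the genes also changed over full-length ZNF384 were chosen after the results were seen, whereas the list and gene tests and the separate empty vector controls were planned. No group had 4 or more libraries, so no single library was tested for standing apart from its group.

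Several lists and genes are picked out because 2 constructs changed them in opposite directions over the empty vector and the difference between the constructs was itself called by edgeR or camera. Cholesterol synthesis genes rose with full-length ZNF384 and fell with the fusions, and the differences had medians of −1.15 for TAF15-ZNF384 (adjusted p = 0.227 with an estimated correlation) and −1.22 for TCF3-ZNF384 (adjusted p = 0.237 with an estimated correlation). MYC targets did the same, with differences of −0.57 (adjusted p = 0.423 with an estimated correlation) and −0.93 (adjusted p = 0.376 with an estimated correlation). With TCF3-ZNF384 this also held for glycolysis and hypoxia at −1.04 (adjusted p = 0.237 with an estimated correlation), G2 and M phase at −0.75 (adjusted p = 0.376 with an estimated correlation) and oxidative phosphorylation at −0.34 (adjusted p = 0.456 with an estimated correlation). The rises were in the full-length ZNF384 libraries, where immediate early genes were also lower than with the empty vector. The 5 non-coding genes took 10.9 and 12.5% of the counts there, against 27.2 and 33.2% with the empty vector. Handling or culture state of that group was not tested for these lists and cannot be told apart from the construct. Not every direction held when a library was left out, although the differences between the constructs did. Without full-length ZNF384 replicate 1 the rise with full-length ZNF384 was no longer called for MYC targets (median 0.03, against 0.46 without replicate 2), G2 and M phase (0.13, against 0.42) or oxidative phosphorylation (0.07, against 0.23), and the median difference between the 2 replicates of that group was −0.35, −0.31 and −0.13. The fall in cholesterol synthesis was no longer called without empty vector replicate 2 (−0.10 with TAF15-ZNF384, −0.28 with TCF3-ZNF384), nor that in glycolysis with TCF3-ZNF384 without its replicate 1 (−0.19) or in oxidative phosphorylation with TCF3-ZNF384 without empty vector replicate 1 (−0.22). The oxidative phosphorylation difference was no longer called after the length and GC correction, at −0.12. Gene by gene, 175 genes changed in opposite directions with full-length ZNF384 and TAF15-ZNF384, and 442 with full-length ZNF384 and TCF3-ZNF384. The fusions opposed each other in 14 genes: Ankrd45, Capsl, Lgr5, Lrp4, Nrgn, Prep and Sla rose with TAF15-ZNF384 and fell with TCF3-ZNF384, and Clec2i, Emp1, Frrs1, Nov, Pik3cg, Pqlc3 and Sept1 did the reverse. Those are 7 genes each way, where unrelated lists of these sizes would share 111 and 127. In size the changes with TAF15-ZNF384 ran from 0.36 ± 0.10 for Prep to −1.42 ± 0.19 for Nov.

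Immediate early genes were lower with full-length ZNF384 than with the empty vector, in 19 of 20 members. The smaller share of the 5 non-coding genes is argued against as the whole cause by a median of −2.47 with total-count scaling without them (adjusted p = 1.32e-26, range 2.10e-66 to 0.145 over the alternatives). Leaving them out shifts all other genes of a library alike, so a median of this size could hardly have been lost in that test. A length and GC bias is argued against by a median of −2.39 after that trend was removed (adjusted p = 6.75e-29, in the same range). Handling or culture state at the sort, to which these genes respond, may account for the difference and cannot be told apart from the construct, because it would follow the group. The largest median difference between replicates of a group was 0.57, in the empty vector, which bounds the spread within groups but not a difference between them.

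Ribosomal protein genes were lower with both fusions than with the empty vector. The camera calls were lost with an estimated correlation (adjusted p = 0.404 with TAF15-ZNF384 and 0.467 with TCF3-ZNF384). The list also varied within both control groups. Its median difference between replicates (replicate 2 minus replicate 1) was −0.28 with the empty vector and −0.25 with full-length ZNF384. That difference was 0.07 with TAF15-ZNF384 and 0.02 with TCF3-ZNF384. A length and GC bias as the whole cause is argued against by medians of −0.76 with TCF3-ZNF384 and −0.50 with TAF15-ZNF384 after that trend was removed. The lower depth of the fusion libraries is argued against by −0.87 and −0.59 at equal counts outside the 5 non-coding genes. Thinning keeps the expected ratio of well-expressed genes, so it covers counting depth only and not how the libraries were made. Reads that moved from the genes to their pseudogenes would raise the 69 tested ribosomal protein pseudogenes, whose median with TCF3-ZNF384 was −0.22, with 23 lower and 1 higher. With TAF15-ZNF384 the median was −0.017, with 17 lower and 3 higher, and such a shift of reads cannot be told apart there, since a median so near 0 over genes that go both ways decides nothing. An effect of the fusions on these genes may remain as an open explanation, and a difference in preparation of the empty vector libraries is limited by the medians of −0.61 and −0.75 over full-length ZNF384.

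Many genes changed in the same direction with both fusions over the empty vector. Noise of the shared empty vector libraries is argued against by a correlation of at least 0.49 when each fusion had a different empty vector library as its control. Separate preparation of the empty vector libraries is argued against as the whole cause for the 67.7% of these genes that changed the same way over full-length ZNF384. The share itself has no reference value. The same fusion libraries were used, and 4320 and 5916 of 12970 genes changed over full-length ZNF384 with TAF15-ZNF384 and TCF3-ZNF384. For the other 390 genes, of which 214 changed the same way in 1 of the fusions over full-length ZNF384, separate preparation cannot be told apart from the fusions, because it would follow the empty vector group. A shared effect of the fusions may therefore account for the larger part, as a hypothesis.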

How the results depend on the processing

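The alternatives that left out or rescaled the 5 non-coding genes, thinned the libraries or removed a length and GC trend were chosen after the results were seen. No gene called in the reported fit was called in the opposite direction under an alternative. Of 162 list results, DESeq2 size factors kept the call and direction of 162, limma-voom of 153, no filter of 148, the replicate block of 157, thinning to equal totals of 153, thinning to equal counts outside the 5 non-coding genes of 155, and the length and GC correction of 152. The estimated correlation kept 96 and ended the other 66, which were all the calls. Of 646 named gene results, the numbers were 638, 614, 639, 645, 606 of 629, 600 of 629 and 600 of 636 in the same order, and the DESeq2 Wald test kept 617 of 644. Fitting only the 2 groups compared raised 3 counts, for TAF15-ZNF384 over the empty vector from 1430 to 2746, TCF3-ZNF384 over the empty vector from 4317 to 5370 and TCF3-ZNF384 over TAF15-ZNF384 from 1308 to 2548. It lowered the 3 with full-length ZNF384, from 2675 to 1787 over the empty vector and from 4320 to 3226 and 5916 to 5119 for TAF15-ZNF384 and TCF3-ZNF384 over it; the spread is then estimated from fewer libraries, and the cause was not tested further. With a replicate block the 6 counts were 2999, 1825, 4655, 4653, 6111 and 1523, and the shared count 1052. Each was above the count reported, and a pairing by replicate number was not excluded. With separate empty vector controls the correlation between the fusions was 0.51 and 0.49, in fits of fewer libraries. Leaving out 1 library, which leaves its group with a lone library, gave 1064 to 3814 genes for full-length ZNF384 over the empty vector, 404 to 686 for TAF15-ZNF384 and 2501 to 2855 for TCF3-ZNF384. It gave 2158 to 5333 for TAF15-ZNF384 and 3866 to 6558 for TCF3-ZNF384 over full-length ZNF384, 371 to 646 for TCF3-ZNF384 over TAF15-ZNF384, 224 to 1638 for the shared count and 0.48 to 0.80 for the correlation. Of 648 list results under these settings 595 kept call and direction, and of 2584 gene results 2117, with 463 losing the call. Turned in direction were the S phase list in full-length ZNF384 over the empty vector, at −0.19 without full-length ZNF384 replicate 1 (adjusted p = 0.0299, range 0.0123 to 0.987) against 0.19 without replicate 2, and Hbb-bs in TAF15-ZNF384 over full-length ZNF384, at −1.86 without TAF15-ZNF384 replicate 1 (adjusted p = 0.821, range 0.00151 to 0.821) against at most 6.51 without another library; the cause was not tested. Depth limits genes near the floor of the shallowest library, where 3 counts correspond to 0.326 CPM.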

Other observations

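The look at Rag2 and the tests of both hypotheses were chosen after the results were seen, whereas the list tests were planned. Lists of other blood cell types and states were not called by camera in any of the 6 comparisons, although single members changed. Over the empty vector with TCF3-ZNF384, T and NK cell genes rose in 4 of 13 members and fell in 2, also adjusted over the list alone, with the transcription factor gene Tbx21 at 3.95 ± 0.52. Stem and progenitor genes rose in 6 of 12 members and fell in 2, or 6 and 3 adjusted over the list alone, with Sox4 at 0.92 ± 0.10 and Mycn at −1.32 ± 0.12. Mature B and plasma cell genes rose in 2 of 13 and fell in 4, also adjusted over the list alone, with the plasma cell regulator gene Prdm1 at 2.77 ± 0.39 and the chemokine receptor gene Ccr7 at −0.65 ± 0.10. Myeloid genes rose in 1 of 11 and fell in 3, also adjusted over the list alone, and both tested macrophage genes fell, also adjusted over the list alone. Interferon response genes rose in 4 of 26 and fell in 1, also adjusted over the list alone, with Gbp2 at 1.63 ± 0.18. For MHC class II the count was 1 of 5 higher and for stromal genes 2 of 7 higher, also adjusted over the list alone. Of 6 erythroid and megakaryocyte genes 1 rose, and 1 rose and 2 fell adjusted over the list alone. With full-length ZNF384, Thy1, a surface protein gene of T cells and fibroblasts, rose by 1.19 ± 0.12 and the interferon regulatory factor gene Irf7 was at −3.18 ± 0.26.

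Rag2, the partner of Rag1 in the recombinase, was higher by 3.99 ± 0.73 with TAF15-ZNF384 (adjusted p = 0.00306) and by 3.42 ± 0.73 with TCF3-ZNF384 (adjusted p = 0.00266) over the empty vector.

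One hypothesis was that the amount of ZNF384 transcript alone sets the response, which rises or falls steadily with the amount. Genes changed by full-length ZNF384, the lowest of the 3 constructs by the rough ranking of reads assigned to Zfp384, would then change the same way with the fusions. Outside the immediate early and NF-kB lists, left out because handling or culture state at the sort may move them, 438 of the 1144 genes changed over the empty vector by both full-length ZNF384 and TCF3-ZNF384 (38.3%), and 173 of 505 with TAF15-ZNF384 (34.3%), went opposite ways. These genes argue against the amount as the sole cause, but not against an amount effect with another effect added. A bound of 10% was set after the shares were seen, so passing it decides nothing. Over all tested genes 294 rose with full-length ZNF384 and fell with TCF3-ZNF384, and 148 did the reverse. Unrelated lists of these sizes would share 238 and 208. In the same direction 352 rose and 360 fell, against 227 and 218. The shares in opposite directions ran from 19.8% (TAF15-ZNF384 without its replicate 1) to 59.5% (TAF15-ZNF384 without full-length ZNF384 replicate 2) over the alternatives. By list, cholesterol synthesis had a median of 0.79 with full-length ZNF384 against −0.19 and −0.43 with TAF15-ZNF384 and TCF3-ZNF384, where the calls with the fusions ended without empty vector replicate 2, at −0.10 and −0.28 (with an estimated correlation, adjusted p = 0.110 with full-length ZNF384, 0.684 with TAF15-ZNF384 and 0.658 with TCF3-ZNF384). A response that turns with the amount, and a culture difference of the full-length ZNF384 group added to an effect of the amount, were not tested and stay open.

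Another hypothesis was that more fusion transcript in the TCF3-ZNF384 cells explains why the genes shared by the fusions moved further there. Of 1207 such genes 928, or 76.9%, had the larger change with TCF3-ZNF384, with median absolute changes of 0.91 and 0.65, and the difference was called by edgeR for 303 genes, of which 291 were larger with TCF3-ZNF384 and 12 with TAF15-ZNF384. More transcript may account for this, but the amount and the fusion partner differ together between these groups and cannot be told apart.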
